A study of Homo sapiens with 4 samples.

How the data were processed

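The series held 4 one-colour arrays labelled with Cy3, 1 for each group: A549 control, A549 labelled GALNT10 knockdown, H322 control and H322 labelled GALNT10 overexpression. Groups were taken from titles, sources and descriptions. The design text gives the knockdown as siRNA in one place and shRNA in another, and states RNA extraction in triplicate without saying whether extracts were pooled, so each array was counted as 1 sample.

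Per the file headers, the deposited scanner files were written by GenePix Pro 6.1.0.4 and hold spot brightness as intensity, with no normalization between arrays and with background taken from negative controls of the block. Per the file headers, saturation is the percent of a spot's pixels at the limit. The deposited series table holds log2 values that the authors brought to nearly equal distributions, with medians of 4.25, 4.25, 4.22 and 4.22, a maximum of 15.83 and a floor of -6.64. How this was done is not given in the sources used here. Its ranks followed the background-subtracted median pixel signal, with Spearman's rho between 0.998 and 0.999.

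The analysis had been laid out for the columns of another scanner program, Feature Extraction. As the files came from GenePix, the background-subtracted median pixel signal took the place of the processed signal, and the deposited spot flag of 100 took the place of the detection column. Each array had 43118 gene spots for 34127 probes, 33128 printed once and 999 printed 10 times. Control spots (1377 per array) and empty spots (725 per array) were left out, as were 63 Y-linked genes and XIST. A probe was detected when at least 50% of its spots had the good flag. Spots of a repeated probe were averaged over good spots where at least 50% were good and otherwise by their median. This was chosen after 3 detected probes on the array labelled knockdown were found to be 2-fold off under the plain mean.

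Each array was scaled to its 75th percentile over gene probes. The raw percentiles were 74, 115, 164 and 213 in the order A549 control, labelled knockdown, H322 control, labelled overexpression, and the negative control medians were 1, 1, 1 and 2. Signals were raised to the lowest signal of detected probes, at 43.98, 30.8, 21.6 and 16.6 after scaling, and a gene undetected on 1 array gave a bound only where its signal there was no higher than this. Saturated probes numbered 26, 21, 9 and 20. Precision came from the SD among the spots of repeated probes at the same signal level. Probes were named from RefSeq annotation by accession (25771), symbol (2207) or synonym (499). The deposited name was kept for 1356 probes and 4294 had none, which gave 21747 gene names. Log2 ratios of several probes of a gene were averaged.

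The comparisons were labelled knockdown against control in A549, labelled overexpression against control in H322, and the control arrays against each other. A gene was measured when a probe was detected on at least 1 array of the pair, and differences of at least 2-fold were counted without a test. The 41 gene lists, with 939 genes, were fixed before the data were examined. A list's median was placed among 10000 random lists of the same size drawn within 20 bins of mean signal. The ratios of the A549 and H322 comparisons were correlated across genes, and the expected overlap was that of independent lists.

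Genes were named by a rule also fixed before the data were examined. It took GALNT10, and for each treatment comparison the 10 largest higher and lower genes detected and unsaturated on both arrays and past 2-fold under 4 other scalings. It added the 5 largest ratios each way of genes detected on 1 array of the pair, up to 4 members of each list, and up to 8 genes that passed 2-fold in both comparisons. For the control arrays it took the 5 largest each way of both kinds and list members. The genes placed in or beside the bright block were singled out after it was found.

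Alternatives planned beforehand were median, quantile and cyclic loess scaling, normexp background correction with an offset of 50, the percentile over probes detected on all arrays, the deposited series values, other filters on dim probes, the brightest probe per gene, and thresholds of 1.5-fold and 3-fold. Alternatives chosen after seeing the data were mean pixel signals, scaling on control spots of the adenoviral sequence E1A, genes with a 10-spot probe or at least 2 probes, and leaving out the bright block, single spots with a pixel coefficient of variation above 40%, or both.

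The steps were tested on simulated data. Of genes simulated 4-fold higher, 100% were found past 2-fold in each comparison, against 92% of those 4-fold lower in the treatment comparisons and 69.6% between the lines. At a simulated 2-fold, 52% and 64% (higher, lower) were found in the knockdown comparison and 36% and 40% in the overexpression comparison. Of unchanged genes, 2 of 9419 (0.02%) and 47 of 11282 (0.42%) passed. The simulated noise was normally distributed at the median spot SD and held no defective or uneven spots. On the real arrays, 0.38% to 2.88% of spot pairs of 1 probe were 2-fold apart, so the simulated shares can be too low. Of lists shifted by 0.3, 95% lay above the random lists, and 3% or 4% of unshifted lists lay outside. Unshifted lists were random genes with independent noise, so this does not cover genes that vary together between cultures. In the data, 13 of 38 lists (knockdown), 9 of 39 (overexpression) and 15 of 39 (lines) lay outside the central 95%. Expected numbers were 1.9, 1.95 and 1.95. The percentiles place a list among random genes and do not test a treatment. The search for bright blocks found 0 spots without a simulated block and 43, 40 and 40 of 48 with one.

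Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.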

Results

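Gene expression was measured with 4 one-colour (Cy3) Agilent-type human arrays, 1 for each of 4 groups. A549 is a human lung adenocarcinoma line and H322 a human bronchioloalveolar lung carcinoma line. The groups were A549 control cells, A549 cells labelled as GALNT10 knockdown, H322 control cells and H322 cells labelled as GALNT10 overexpression. GALNT10 encodes a polypeptide N-acetylgalactosaminyltransferase, one of the enzymes that start mucin-type O-glycosylation. The study asked what raising or lowering this enzyme does to growth, invasion and apoptosis of lung cancer cells. Each array held 34127 gene probes, of which 34.5% were detected (at least 50% of their spots flagged good) on the A549 control array, 39.5% on the A549 knockdown array, 43.0% on the H322 control array and 45.4% on the H322 overexpression array. The cell line field of the labels read A549 for all 4 samples, while titles, sources and descriptions named H322 for 2 of them. Across the 10553 probes detected on every array, Pearson's r was 0.99 between the A549 arrays, 0.98 between the H322 arrays, and between 0.87 and 0.88 for arrays of different lines.

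With 1 array per group there was no replicate check on any difference and no test was possible. The values below are log2 ratios of pairs of arrays, and the words higher and lower describe those arrays. The only error that could be measured was the spread among spots of 1 probe printed 10 times, whose median SD on the log2 scale was 0.21 on the A549 control array, 0.22 on the A549 knockdown array, 0.32 on the H322 control array and 0.20 on the H322 overexpression array. It is given after ± for single genes and holds no variation between cultures. Of pairs of spots of 1 such probe on 1 array, 0.99%, 0.38%, 2.88% and 0.68% were at least 2-fold apart, in the same order of arrays. Where a gene was not detected on 1 array of a pair and its signal there was no higher than the lowest signal of a detected probe, its ratio is a lower bound against that lowest signal, written "at least", and it is counted at that bound. Where the undetected spot was brighter than that, the ratio was taken to the spot's own signal, is no bound, and is marked "against an undetected spot". A mean over probes that includes an undetected one is marked "in part undetected" and has no ±.

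The targeted gene was read by 1 single-spot probe, A_33_P3703501, detected on every array. On the array labelled knockdown its scaled signal was 185, against 189 on the A549 control array, a log2 ratio of -0.04 ± 0.30. On the array labelled overexpression it was 116, against 87.1 on the H322 control array, a log2 ratio of 0.42 ± 0.41. The difference between the A549 arrays was smaller than the spot noise, and that between the H322 arrays was about as large as it, or 0.85 under scaling on control spots. GALNT10 was 2.17-fold higher in A549 control than in H322 control cells (log2 ratio 1.12 ± 0.41). Its raw signals there were 99 and 101, so this difference appeared only after scaling for the brightness of the arrays. Before scaling, E1A control spots were lower on the A549 control array than on the H322 control array (log2 ratio -0.89). Median scaling moved the middle of all genes in that comparison by -0.46, and scaling on control spots by -0.26. Both shifts were smaller than the ratio, so its size but not its direction depended on the choice between these and the main scaling. The files do not say which part of the transcript the probe matches, so it may lie outside an introduced coding sequence. Because the knockdown was not visible in GALNT10, the treated arrays are called by their labels throughout.

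**Figure D1:**
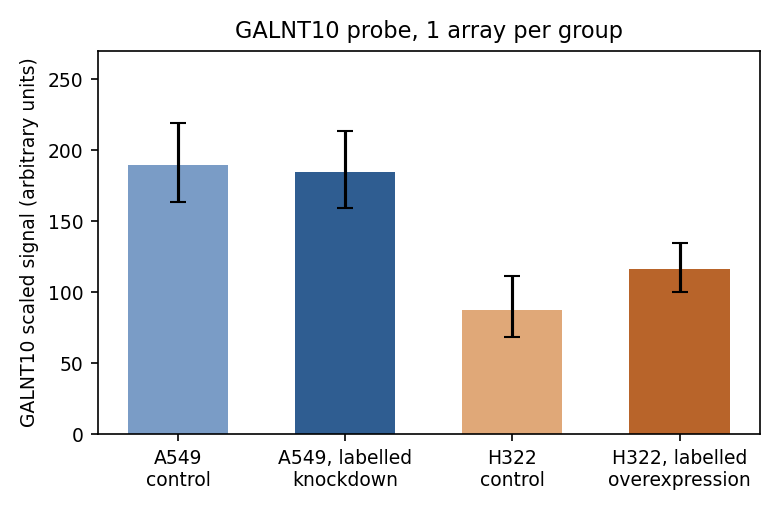
Bars show the scaled signal of the GALNT10 probe (vertical axis, arbitrary units, starting at 0) on the 4 arrays, and error bars show 1 SD of spot noise at that signal level. The A549 arrays stood at 189 and 185 and the H322 arrays at 87.1 and 116.

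In A549, the array labelled knockdown showed higher signals for genes induced by low oxygen and for inflammatory cytokines. NDRG1, a stress-induced gene of the hypoxia response, was 5.47-fold higher (log2 ratio 2.45 ± 0.29). ANKRD37, a target of hypoxia-inducible factor, was 3.92-fold higher, and the cytokine gene IL6, on a 10-spot probe, was 3.84-fold higher (log2 ratio 1.94 ± 0.09). Lower signals were fewer and smaller once a local defect of the control array was set aside, and included CHAC1 and ASNS, amino acid stress genes under ATF4. Of 10061 measured genes, 56 were at least 2-fold higher and 45 at least 2-fold lower, while 95.4% differed by less than 1.5-fold.

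The hypoxia and glycolysis list had 9 of 28 measured members at least 2-fold higher and none lower, with a median log2 ratio of 0.58. That median lay above all 10000 random lists of equal size and signal (percentile 100). Its largest members after NDRG1 and ANKRD37 were PFKFB4, which makes an activator of glycolysis (1.58 ± 0.34), and ANGPTL4, an inhibitor of lipoprotein lipase (2.90-fold higher). HILPDA (1.69 ± 0.28), a lipid droplet protein, ALDOC (1.51 ± 0.30), a glycolytic aldolase, and ADM (1.44 ± 0.09), the precursor of the peptide adrenomedullin, were also among the 10 largest. Among NF-kB cytokines and chemokines, 5 of 18 measured members were at least 2-fold higher and none lower (median 0.63, percentile 100). Besides IL6 these included the chemokines CXCL2 (1.43 ± 0.20) and, both against undetected spots, CCL20 (2.65-fold) and the cytokine IL1B (2.40-fold).

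Of 24 measured immediate early genes, 3 were at least 2-fold higher: IER3 (1.54 ± 0.20), the phosphatase gene DUSP5 (at least 2.66-fold) and ZFP36 (1.01 ± 0.30), which promotes decay of cytokine mRNAs. The list median was 0.22 (percentile 99.9). TGF-beta targets had 2 of 13 members at least 2-fold higher, INHBA (1.04 ± 0.09) and ID3 (1.01 ± 0.29), with a median of 0.30 (percentile 99.96). The type I interferon list had 2 of 19 members higher, OASL (at least 4.50-fold) and ISG15 (1.48 ± 0.29), with a median of 0.16 (percentile 97.7). Lists without a single member past 2-fold also stood apart: cholesterol synthesis at 0.26 (percentile 100), heat shock proteins at 0.22 (percentile 99.97), fatty acid synthesis at 0.18 (percentile 99) and proteasome at 0.13 (percentile 99.5).

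Among lists with at least 3 measured genes, the ATF4 and amino acid starvation list was the lowest, at a median of -0.27 below all random lists (percentile 0.0), with 2 of 18 members at least 2-fold lower. These were CHAC1, which degrades glutathione (-1.39 ± 0.29), and ASNS, asparagine synthetase (-1.09 ± 0.29). PHGDH and PSAT1, enzymes of serine synthesis, had log2 ratios of -0.74 and -0.73. Ribosomal proteins had a median of -0.11 (percentile 0.48), replication-dependent histones of -0.07 (percentile 2.1) and aldehyde dehydrogenases and cytochromes P450 of -0.10 (percentile 2.1). Median scaling, which raised all genes and so the random lists by 0.25, put these 3 medians at 0.14, 0.14 and 0.15. Normexp, which raised the middle of all genes by 0.09, put the ribosomal median at 0.083 and the histone median at 0.024. The ribosomal median also turned to 0.011 under quantile scaling and 0.01 with the deposited series values, where all genes moved by -0.02 at the median. The histone median turned to 0.053 over genes with a 10-spot probe or at least 2 probes. The direction of these 2 lists was therefore not stable.

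Genes of growth, death and invasion moved little on these arrays. None of 30 measured DNA replication genes, 34 G2/M and mitosis genes, 19 pro-apoptotic genes, 10 anti-apoptotic genes or 15 p53 targets was counted past 2-fold, the nearest being the anti-apoptotic BIRC3, at least 1.99-fold higher. The same held for 15 matrix proteases and inhibitors, 18 integrins and basement membrane genes, 11 mesenchymal genes and 10 epithelial adhesion genes. Their medians ranged from -0.06 for integrins to 0.12 for anti-apoptotic genes, and none lay outside the central 95% of random lists. None of the 9 other measured polypeptide GalNAc-transferases (median 0.09) or 10 O-glycan extension enzymes (median 0.03) differed by 2-fold. The mucin gene MUC1 was higher, at 1.14 ± 0.34.

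The largest lower values came from 1 place on the A549 control array. A block of 35 spots in rows 139 to 144 and columns 2 to 9 was picked because at least 30% of the spots around each were at least 2-fold lower on the array labelled knockdown. Of the 35 spots, 24 were themselves at least 2-fold lower, and 15 of the 45 lower genes lay in the block. They included KAT7 (10.2-fold lower), FLJ30901 (5.97-fold), KIFC1 (4.49-fold), SNTG1 (at least 16.7-fold), ZMYND15 (at least 16.2-fold), CFAP263 (at least 14.4-fold) and CELA1 (at least 11.2-fold). A further 4 lower genes lay within 2 rows and 3 columns of the block, ATG9B (at least 13.2-fold lower), OSBP2, STRN3 and TEX19. Outside it, RNA5-8SN5, a 5.8S ribosomal RNA gene, was the only other gene that met the rule for large lower values (-1.48 ± 0.28). Among the largest ratios with an undetected control spot, CHGA (at least 45.2-fold higher), CPNE2 (at least 10.8-fold), and, against undetected spots, EGLN1 (2.95-fold) and BIN3 (2.82-fold) rested on control spots with uneven pixels, whose coefficients of variation were 108%, 89%, 61% and 60% against a 99th percentile of 40% among good spots. Leaving out the block, but not the spots beside it, and single spots above 40% left 35 higher and 20 lower genes, and median scaling gave 136 higher and 26 lower (scaling on control spots 118 and 28, with a shift of 0.19).

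**Figure D2:**
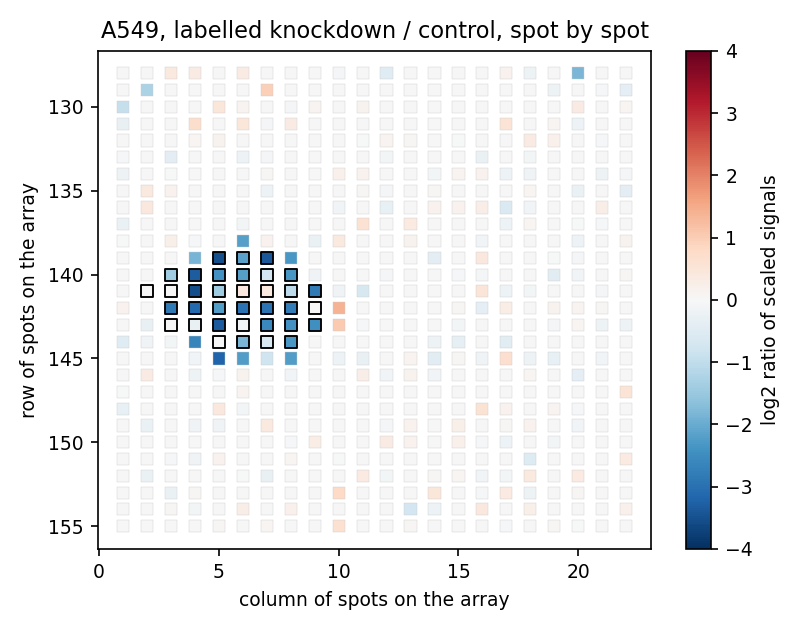
Each square is 1 spot at its row and column on the array surface, coloured by the log2 ratio of scaled signals, the array labelled knockdown over A549 control, with signals raised to a floor of 43.98. Black outlines mark the 35 spots around which at least 30% of the spots were at least 2-fold brighter on the control array, and further blue spots lie beside them.

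In H322, the array labelled overexpression showed higher interferon-stimulated genes. OASL was 6.05-fold higher (log2 ratio 2.60 ± 0.40), the exonuclease gene ISG20 5.08-fold (2.34 ± 0.36) and the ubiquitin-like modifier ISG15 4.03-fold (2.01 ± 0.37). IFI27 was detected on the array labelled overexpression alone, at least 12.04-fold higher. Among the lower genes, the aldehyde dehydrogenase ALDH3A1 stood at -1.86 ± 0.41 and PI3, the elastase inhibitor elafin, at -1.67 ± 0.38. Of 11687 measured genes, 146 were at least 2-fold higher and 217 at least 2-fold lower, and 84.2% differed by less than 1.5-fold. The share past 2-fold was 3.11%, against 2.88% between spots of 1 probe on the control array and 0.68% on the array labelled overexpression. Here too the count alone does not set the label apart from spot noise.

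Type I interferon genes had 6 of 24 measured members at least 2-fold higher and none lower, with a median of 0.30 (percentile 99.9). IFI16, a DNA sensor outside that list, was 2.92-fold higher (1.54 ± 0.40). NF-kB cytokines and chemokines had 2 of 19 members past 2-fold, CCL5 (at least 6.25-fold higher) and IL6 on its 10-spot probe (1.49 ± 0.12). Their median of 0.33 (percentile 99.9) turned to -0.12 when only genes with a 10-spot probe or at least 2 probes were kept. Immediate early genes had the highest median among lists with at least 3 measured genes, 0.46 (percentile 100), with JUN at 1.20 ± 0.40 and, in the other direction, FOS at least 2.13-fold lower. YAP/TAZ targets had a median of 0.22 (percentile 98.1), with FJX1 (2.17 ± 0.40) and TGFB2 (2.07-fold, against an undetected spot) past 2-fold.

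Cholesterol synthesis (0.32, percentile 99.9), heat shock proteins (0.22, percentile 98.97) and hypoxia and glycolysis (0.19, percentile 99.4) also stood above their random lists. In these lists PFKFB4 alone passed 2-fold (1.22 ± 0.40), and LSS, a cholesterol synthesis enzyme, was 1.99-fold higher (in part undetected). Lists of stress genes held single large members without a shifted median. In the endoplasmic reticulum stress list (median -0.01), the transcription factor DDIT3 was 3.38-fold higher against an undetected spot and PPP1R15A 2.03-fold higher. In the ATF4 list (median 0.09), STC2 stood at 1.53 ± 0.41 and CTH, which makes cysteine, at -1.02 ± 0.38.

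Of 25 measured NRF2 targets, 4 were at least 2-fold lower and none higher: ALDH3A1, PGD of the pentose phosphate pathway (2.70-fold lower, against an undetected spot with a scaled signal of 653), the transporter gene ABCC3 (-1.15 ± 0.26) and AKR1B10 (-1.08, in part undetected). The list median was -0.05 (percentile 36.2), so the other members did not move with them. Replication-dependent histones had a median of -0.19 (percentile 1.6), with H2AC13 at -1.06 ± 0.37, and scaling on control spots, which raised all genes by 0.43, put it at 0.24. Fibroblast markers had a median of -0.54 over 6 measured genes (percentile 0.75), with decorin, DCN, 3.70-fold lower against an undetected spot. The mucin gene MUC16 stood at -1.30 ± 0.41 and the Wnt ligand gene WNT6 at -1.91 ± 0.38.

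The genes that bear on growth and death again gave few 2-fold differences. None of 34 DNA replication genes passed, and of 34 G2/M and mitosis genes only the checkpoint kinase BUB1 did, at 1.27 ± 0.36. Of 23 pro-apoptotic genes, HRK was higher (1.16 ± 0.41) and CASP9 lower (-1.18 ± 0.38), and of 11 anti-apoptotic genes the decoy receptor TNFRSF10C was lower (-1.64 ± 0.41). Mesenchymal genes had 2 of 15 members higher, the smooth muscle gene TAGLN (1.58, in part undetected) and the transcription factor SNAI2 (1.21 ± 0.41), with a median of 0.19 (percentile 94.4). Among integrin and basement membrane genes, the collagen gene COL4A6 was higher (1.01 ± 0.41). The medians of these lists lay within the central 95% of random lists. None of 6 other GalNAc-transferases or 12 O-glycan extension enzymes passed 2-fold.

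Other large differences between the H322 arrays were SPOCK1, a matrix proteoglycan (2.12 ± 0.40), the protease inhibitor SPINK1 (1.71 ± 0.40), the actin-binding NEXN (1.68 ± 0.27), IFRD1 (1.56 ± 0.37) and CD68 (1.38 ± 0.37), as well as LINC00520 (at least 5.79-fold higher) and the receptor gene IL7R (4.96-fold, against an undetected spot). MRPL40 was 14.5-fold higher against an undetected spot with a pixel variation of 82%. Lower genes included IMP3 (8.12-fold), POT1 (6.93-fold), ASPG (6.13-fold), RNA5-8SN5 (3.99-fold), MYLIP (3.46-fold), KLHDC9 (3.38-fold), SCARNA9 (3.19-fold) and the defensin gene DEFB1 (3.18-fold), each on 1 spot. Not detected with the overexpression label were KIFC1 (at least 11.9-fold lower), TM4SF4 (at least 4.47-fold), OR51A7 (at least 4.10-fold) and STRN4 (3.24-fold, against an undetected spot with a pixel variation of 90%). Median scaling gave 193 higher and 177 lower genes, and scaling on control spots gave 909 higher and 45 lower.

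**Figure D3:**
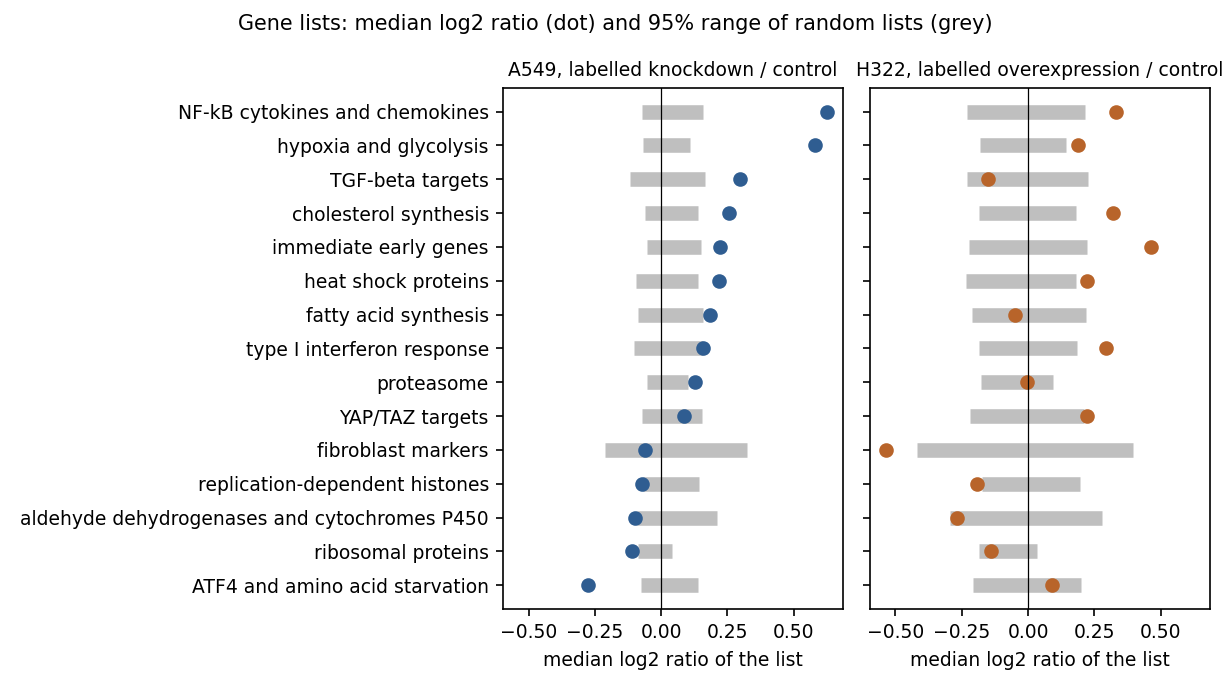
Dots show the median log2 ratio (horizontal axis) of each gene list that lay outside the central 95% of random lists in at least 1 comparison, and grey bars show that 95% range over 10000 random lists matched on size and signal. The left panel is the A549 array labelled knockdown over control and the right panel the H322 array labelled overexpression over control. NF-kB, hypoxia, cholesterol, immediate early, heat shock and interferon lists lay to the right of their grey bars in both panels. The interferon median in A549 did so only just, at 0.1591 against a limit of 0.1565. The NF-kB median in H322 turned to -0.12 over genes with a 10-spot probe or at least 2 probes.

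Opposite changes of the GALNT10 level would be expected to move genes that it drives in opposite directions, so the comparisons were set against each other. GALNT10 itself stood at -0.04 ± 0.30 in A549 and 0.42 ± 0.41 in H322. Opposite changes were thus not seen on these arrays, and the comparison cannot decide whether GALNT10 drives these genes. They share no array. Across 9386 genes measured in both, the log2 ratios were positively correlated, with Pearson's r = 0.28 and Spearman's rho = 0.29, across genes that are not independent replicates. No gene was at least 2-fold different in opposite directions. Independent lists would give 0.58 genes higher with the knockdown label and lower with the overexpression label, and 0.24 the other way. With so few expected, the absence of such genes carries little weight. In the same direction, 6 genes were at least 2-fold higher in both, against 0.46 for independent lists, and 4 were lower in both, against 0.30.

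The 6 higher in both were the interferon genes OASL (at least 4.50-fold and 6.05-fold) and ISG15 (2.79-fold and 4.03-fold), the cytokine gene IL6 (3.84-fold and 2.81-fold), PFKFB4 (2.99-fold and 2.33-fold), the neuropeptide precursor gene VGF (2.08-fold and 2.68-fold) and PDCD11, involved in ribosomal RNA processing (2.06-fold and 2.63-fold, each against an undetected spot). The 4 lower in both were RNA5-8SN5 (2.79-fold and 3.99-fold), KRTAP3-3 (2.28-fold and 3.35-fold), FLJ44342 (2.13-fold and 2.40-fold) and KIFC1, whose spot lay in the bright block of the A549 control array. NF-kB, hypoxia, cholesterol, immediate early, heat shock and interferon lists lay above the central 95% of random lists in both comparisons, and replication-dependent histones below it. Of these, the interferon median in A549 was at the edge of that range, at 0.1591 against an upper limit of 0.1565. The NF-kB median in H322 turned negative over genes with a 10-spot probe or at least 2 probes. The histone median in A549 turned positive under the limit to such genes. Median scaling in A549 and scaling on control spots in both lines also made the histone medians positive, by raising all genes alike. Normexp made the A549 histone median positive as well, and raised the middle of all genes there by 0.09. ATF4 genes were low in the knockdown comparison alone, and the difference between the comparisons was not tested.

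**Figure D4:**
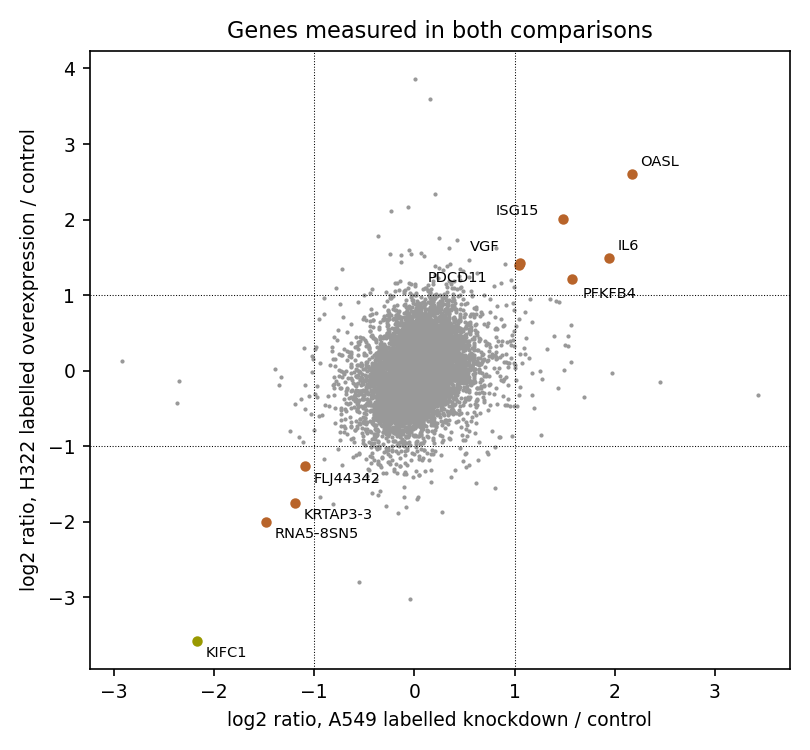
Each point is 1 gene, placed by its log2 ratio in A549 (labelled knockdown over control, horizontal axis) and in H322 (labelled overexpression over control, vertical axis), with dotted lines at 2-fold. The 10 labelled genes passed 2-fold in the same direction in both, the upper left and lower right corners hold none, and the olive point KIFC1 lay in the bright block.

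The control arrays gave the difference between the lines against which the treatments can be set. A549 control cells were far higher in AKR1B10, an aldo-keto reductase (695-fold, log2 ratio 9.44 ± 0.29), and in keratin KRT19 (at least 2636-fold), osteopontin, SPP1 (at least 1161-fold), and the transcription factor gene TBXT (at least 661-fold). H322 control cells were higher in ANXA8L1 (at least 421-fold), LY6K (at least 298-fold), placental alkaline phosphatase, ALPP (at least 174-fold) and the secreted protease inhibitor SLPI (40.05-fold). Of 10857 measured genes, 1770 were at least 2-fold higher in A549 and 1473 in H322.

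NRF2 targets were the most shifted large list, with 15 of 25 members at least 2-fold higher in A549 and none lower (median 1.65, percentile 100), among them ALDH3A1 (5.03) and AKR1C1 (3.45), both in part undetected. Immediate early genes (median 1.64, percentile 100; DUSP6 146-fold, against an undetected spot), endoplasmic reticulum stress genes (0.83, percentile 100) and ATF4 genes (0.73, percentile 99.9) were also higher in A549. Alveolar and club cell markers had a median of 1.16 (percentile 99.8) over 8 genes, with HOPX at least 130-fold higher, and ribosomal proteins (0.61) and oxidative phosphorylation (0.50) had percentiles of 98.9 and 98.7. Higher in H322 were DNA replication genes (-0.88, percentile 0.0; 15 of 33 at least 2-fold), G2/M genes (-0.48, percentile 0.37), Wnt targets (-0.96, percentile 0.79), and, each turning positive when only genes detected in both lines were kept, which leaves out members undetected in A549, epithelial adhesion genes (-0.80, then 0.51), interferon genes (-0.75, then 0.91) and Notch targets (-1.47, then 0.03). CDKN2A, described as deleted in A549, was lower in A549 (-4.63, in part undetected), but 1 of its 2 probes was detected there at a scaled signal of 342, against a lowest detected signal of 43.98. MTAP beside it was not lower (0.78 ± 0.24). Among GalNAc-transferases, GALNT14 (at least 69.6-fold), GALNT16 (at least 23.1-fold) and GALNT5 (at least 9.57-fold) were higher in A549, and the list median of 1.59 became -1.43 over genes with a 10-spot probe or at least 2 probes.

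Other large differences between the lines in A549's favour were MLLT11 (186-fold), TFPI2 (57.6-fold), UCHL1 (46.5-fold), TMX4 (45.0-fold), IGFBP2 (at least 614-fold) and AGR2 (at least 600.4-fold). In H322's favour they were ARHGAP45 (39.0-fold), SEMA3B (35.4-fold), PODXL (30.7-fold), FBXO2 (28.5-fold), CDKN1C (at least 160-fold) and RBP4 (at least 147-fold). Median scaling moved the middle of all genes by -0.46 and gave 1091 genes higher in A549 and 2817 higher in H322, and scaling on control spots gave 1318 and 2150.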

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

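The tests of exchanged labels, spot noise, the bright block, uneven spots and inner against outer places were chosen after the result was seen; the others were written down beforehand.

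Control spots for the adenoviral sequence E1A, which entered only the alternative scaling and not the main values, differed between arrays before scaling. Over 6 probes their log2 ratio was 0.45 ± 0.07 (SD over probes) on the array labelled knockdown and -0.053 ± 0.14 on the array labelled overexpression, each against its control. The 75th percentile of gene probes differed by 0.64 and 0.38 on the same arrays. Whether equal amounts of control RNA were added is not given in the sources used here.

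GALNT10 was not lower on the array labelled knockdown. An exchange of the A549 labels after a 2-fold knockdown that the probe could read would give a ratio near 1, and the ratio was -0.037. If the knockdown was weaker, lost or not read by the probe, this cannot tell exchanged labels from correct ones. A 2-fold lower level would put the ratio at -1, and the ratio lay 3.24 SD of spot noise above that. Spot noise of the usual size would therefore not hide such a level. The SD came from other probes and this probe had 1 spot per array, so a spot defect stays open. A knockdown of less than 2-fold, a probe on a transcript form that was not targeted, and a loss of knockdown before RNA extraction stay open and were not tested.

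The log2 ratios of the A549 and H322 comparisons were weakly and positively correlated (r = 0.28), although the labels name opposite interventions. Dim probes alone do not carry this, as r was 0.32 among the brightest genes. Neither do the interferon, NF-kB, hypoxia and immediate early lists alone, as r was 0.27 without them. Both treated arrays were brighter than their controls before scaling (75th percentiles 115 against 74 and 213 against 164). Whether this contributes, also among bright genes, was not tested. A steady trend along the slide would give opposite ratios, since the treated arrays lay 1 place to opposite sides of their controls (-1 and 1). That rests on the layout alone and does not cover uneven effects of place. An effect of inner against outer places cannot be told apart from treatment, because the 2 treated arrays held the inner places. A response to introducing nucleic acid or to selection, shared by both lines, may contribute and was not tested.

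Most of the largest differences sat on probes printed once. Among probes detected on both arrays, 0.54% of single-spot and 0.84% of 10-spot probes passed 2-fold in the knockdown comparison, and 2.70% and 1.26% in the overexpression comparison. This leaves spot defects open in both, against the bound set beforehand for the knockdown comparison, since only 4 of 476 10-spot probes passed there (95% interval 0.327% to 2.14%) and genes undetected on 1 array were not counted. The bright block, with 15 of the genes lower with the knockdown label, was made of 35 spots picked by their neighbours, against at most 0 in 100 shuffles of the spot positions, and 34 of the 35 met the rule against the H322 control array as well. The other lower genes stay open. Uneven spots taken as dim made up 52.2% of the undetected spots behind 2-fold ratios in the knockdown comparison, against 20.5% behind smaller ratios, and 39.9% against 17.96% in the overexpression comparison. In the knockdown comparison the excess lay with undetected control spots, 31 of 37 against 235 of 1048 at any ratio. For undetected spots with the knockdown label it was 5 of 32, against 33 of 152. In the overexpression comparison it was 30 of 71 on the control side and 31 of 82 on the other. Uneven spots may account for part of the higher ratios in A549 and of ratios both ways in H322.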

How the results depend on the processing

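Mean pixel signals, scaling on control spots, the limit to genes with a 10-spot probe or at least 2 probes, and leaving out bright or uneven spots were chosen after seeing the data. Of 523 single-gene values other than those of GALNT10, none of at least 2-fold changed sign under an alternative that could compute it. This was largely fixed beforehand and is no support for these values. The largest shift of the middle of all genes was -0.46, and the largest genes were chosen for passing under 4 other scalings. Of list medians outside their random lists, 17 values under alternatives reversed. Those under median scaling and scaling on control spots follow from the shift of all genes, random lists included. The shift was 0.25 and 0.19 with the knockdown label, and 0.43 with the overexpression label under control spots. Those when detected on both arrays leave out members undetected in 1 line. For the others the cause was not tested, though normexp raised the middle of all genes with the knockdown label by 0.09. The GALNT10 ratio ranged from -0.08 to 0.21 with the knockdown label, turning positive under median scaling, normexp, mean pixel signals and scaling on control spots by less than its spot noise of 0.30, and from 0.26 to 0.48 with the overexpression label except under scaling on control spots (0.85). Of 101 genes past 2-fold in the knockdown comparison, alternatives gave 162 under median scaling, 50 under normexp, 47 when detected on both arrays, 9 with a 10-spot probe or at least 2 probes, 66 without uneven spots and 55 without uneven spots and the bright block. For the overexpression comparison (363) they gave 93 under normexp, 196 without a filter on dim probes, 954 under scaling on control spots and 46 with a 10-spot probe or at least 2 probes. Between the lines (3243) they gave 2083 under normexp, 2032 when detected on both arrays and 632 with a 10-spot probe or at least 2 probes. Most of the drop with probe number comes from testing fewer genes, as 7903 of 10061, 8697 of 11687 and 8432 of 10857 measured genes rested on 1 single-spot probe. Past 2-fold these were 92 of the 101, 317 of the 363 and 2611 of the 3243. That is a larger share than among measured genes, more so in the treatment comparisons. Genes with more spots thus also passed 2-fold less often. For this and for the other alternatives the cause was not tested. At 1.5-fold the counts were 464, 1851 and 5623, and at 3-fold 28, 45 and 1686. Genes past 2-fold in the same direction in both treatment comparisons (10) numbered 17 under median scaling, 6 under normexp, 29 under scaling on control spots, 1 with a 10-spot probe or at least 2 probes, 82 at 1.5-fold and 2 at 3-fold. Genes in opposite directions (0) numbered 1 under median scaling and 23 at 1.5-fold. The correlation of 0.28 stayed positive under every alternative, at 0.33 under normexp, 0.26 with the series values, 0.30 when detected on both arrays, 0.20 without a filter, 0.29 with mean pixel signals, 0.31 with a 10-spot probe or at least 2 probes, 0.30 without uneven spots and 0.30 without uneven spots and the bright block. In the knockdown comparison, ribosomal proteins turned to 0.14 under median scaling, 0.011 under quantile scaling, 0.083 under normexp, 0.01 with the series values and 0.081 under scaling on control spots. Histones turned to 0.14 under median scaling, 0.024 under normexp, 0.084 under scaling on control spots and 0.053 with a 10-spot probe or at least 2 probes, and aldehyde dehydrogenases and cytochromes P450 to 0.15 under median scaling and 0.0899 under scaling on control spots. In the overexpression comparison, NF-kB genes turned to -0.12 with a 10-spot probe or at least 2 probes, and histones to 0.24 under scaling on control spots. Between the lines, GalNAc-transferases turned to -1.43 with a 10-spot probe or at least 2 probes, and when detected on both arrays epithelial genes turned to 0.51, interferon genes to 0.91 and Notch targets to 0.033. No paired analysis was possible because each group had 1 array. Filters on dim probes were not run for the GALNT10 ratios, as its probe was detected on every array. Signal over background limited the gene set, with 34.5% to 45.4% of probes detected.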

Other observations

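Several lists that bear on cell identity held genes past 2-fold. With the knockdown label, the neuroendocrine list held CHGA, whose control spot was uneven, and ENO2, a glycolytic enzyme, at 1.33, and ALDH2, a mitochondrial aldehyde dehydrogenase, was 2.03-fold lower against an undetected spot. With the overexpression label, the Notch target HES5 stood at 1.27, HLA-DMA, which loads peptides on MHC class II, at -1.11, the endothelial adhesion gene ESAM at 1.08 and CYP1B1 at 1.01 as the mean of 2 probes, 1 of them undetected on the control array.

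Between the control arrays, neuroendocrine markers had a median of 3.23 over 4 measured genes (percentile 99.98 among random lists), with UCHL1 at 5.54 and NCAM1 at least 20.4-fold higher in A549. Mucin genes were split, with MUC4 at 1.79 and MUC1 at -2.56. The p53 targets FDXR (2.49) and GDF15 (1.40) were higher in A549, with a list median of 0.50 (percentile 95.1), and the cancer-testis genes MAGEA6 (-2.87) and MAGEA12 (-2.58) were higher in H322.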
